A study of Mus musculus with 35 samples.

How the data were processed

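Astrocyte-enriched cells were taken from the hypothalamus, hippocampus and cortex of male C57BL/6JRj mice, and their RNA was sequenced in 35 libraries that form 6 groups of region and diet. Per the labels, mice received standard chow (SC) or a high-fat high-sugar diet (HFHS, 58%) from 8 to 9 weeks of age for 4 months, and tissue of 2 animals was pooled into each replicate. Per the labels' protocols, cells were separated with magnetic beads against ACSA2, an astrocyte surface antigen encoded by Atp1b2, and cDNA was made with the SMART-Seq v4 Ultra Low Input kit, which does not keep strand. Per the same protocols, hypothalamus and hippocampus cells passed over MS columns with standard reagent volumes, and cortex cells over LS columns with larger volumes. Column and volume therefore cannot be separated from region in any comparison with cortex.

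The deposited files give an estimated count and a TPM value for each transcript of each library, which the authors made with Salmon on build GRCm38, per the submitters' processing notes. Those notes also name FastQC. The versions of both tools, the read trimming and the transcript set are not given in the sources used here. Of 140948 transcripts in the files, 139852 matched GENCODE mouse release 21 and 1096 did not. The unmatched transcripts held between 0.214% and 0.535% of the estimated counts of a library and were left out. Estimated counts were summed over the transcripts of each of 54119 genes and rounded to whole numbers, and gene symbols were taken from the same annotation. Counts that Salmon divides between paralogs, pseudogenes, overlapping genes or genes on opposite strands remain uncertain for the single gene. The total per library lay between 47578560 and 65982495 reads. Deposited TPM values served in the alternative forms of the counts and of the cell type scores.

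Genes were compared with edgeR 4.0.16 in R 4.3.3, with the filterByExpr filter on the groups compared, TMM scaling and the robust quasi-likelihood test. P values were adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. HFHS was compared with SC within each region on the libraries of that region alone, which left 19272 genes in hypothalamus, 19036 in hippocampus and 17844 in cortex. The difference of the diet effect between regions (interaction contrast) and the difference between regions on SC were taken from 1 model of all 6 groups and 21574 genes. Log2 fold changes are the fitted values of edgeR. Their standard errors (SE) are the size of the fold change divided by the square root of the F statistic. The SE of an interaction or a region difference therefore rests on the fit of all 6 groups. Log2 CPM values carry a prior count of 2. Expression is given as mean CPM (counts scaled by library size) ± SD over replicates. Since each replicate is a pool, the SD measures the spread between pools.

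A total of 41 gene lists (cell type markers, region markers and pathways) were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison. Lists with fewer than 4 measured members were not tested. For each list, members past the threshold were counted over all genes tested and adjusted over the list alone. The mean log2 CPM of each of the cell type lists served as a score per library, and scores were compared between diets by exact two-sided permutation tests, adjusted over all lists and regions. Genes named in the text follow a rule. These are the 10 largest and 10 smallest log2 fold changes among genes past the threshold with a mean log2 CPM of at least 3 and a symbol other than a clone or predicted gene name, or the 5 smallest p values where fewer than 5 passed. The rule adds up to 4 members with the smallest p of each list described, and Atp1b2, Gfap and Aqp4 in every comparison. A few genes that meet the rule are not described here. The groups, the comparisons, the tests, the lists, the rule and most alternatives were fixed before the data were examined.

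The procedure was tested on simulated data with 200 changed genes. In the simulated hypothalamus diet comparison, on 19272 genes, 47% of the changes of 2-fold and 99% of those of 4-fold were recovered. The shares were 41% and 84% on the 19036 genes in hippocampus, and 11% and 80% on the 17844 genes in cortex, where a change of 2-fold would usually have been missed. The shares for the interactions, on 21574 genes, were 10% and 70% for hypothalamus against cortex, 10% and 62% for hippocampus against cortex, and 13% and 67% for hypothalamus against hippocampus. For the regions on SC they were 42% and 96%, 34% and 89%, and 38% and 94% in the same order. Of the genes called in the simulation, 0%, 6% and 3.2% were false for diet in hypothalamus, hippocampus and cortex. The false shares were 3.6%, 6.5% and 11.1% for the interactions and 3.5%, 2.4% and 2.9% for the regions, in the same order.

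The alternatives fixed in advance were DESeq2 1.42.0, voom with sample quality weights, other scaling, no filter on low counts, an adjusted p of 0.10, counts from length-scaled TPM, a fit of all 6 groups or of the 2 groups alone, a surrogate variable from sva 3.50.0, a principal component of the cell type markers as a covariate, the replicate number as a block, camera with an estimated correlation, fry, and each replicate left out in turn. For the interactions and the regions on SC, the block was the replicate number within each diet. Chosen after seeing the data were fits without 3 libraries of short mean transcript length, with mean transcript length as a covariate, with an offset per bin of GC content, and with a score of genes that vary together with Dapk3 as a covariate. The score is the mean log2 CPM of 219 genes whose correlation with Dapk3 exceeds 0.9 among the hippocampus libraries after the mean of each diet is subtracted. Permutations, figures and tables were made with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.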

Results

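RNA of cells sorted for ACSA2 was measured in 6 hypothalamus, 5 hippocampus and 6 cortex replicates from mice on SC, and in 5, 7 and 6 replicates from mice on HFHS. Each replicate pooled 2 mice. The libraries held between 47578560 and 65982495 reads assigned to transcripts. The design asks how the astrocyte-enriched fraction of each region responds to the diet, and how the regions differ.

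The sorted fractions held transcripts of several cell types, and their share differed by region. On SC, the score of astrocyte markers (mean log2 CPM of 18 genes) was 10.27 ± 0.31 (SD, n = 6) in cortex, 8.32 ± 0.32 (n = 6) in hypothalamus and 7.95 ± 1.01 (n = 5) in hippocampus. The oligodendrocyte score was 11.09 ± 0.49 in hippocampus, 10.17 ± 0.42 in hypothalamus and 9.33 ± 0.53 in cortex. Markers of ependymal cells, the ciliated cells that line the ventricles, scored 7.95 ± 0.39 in hypothalamus, 6.41 ± 0.49 in hippocampus and 3.40 ± 0.77 in cortex.

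**Figure D1:**
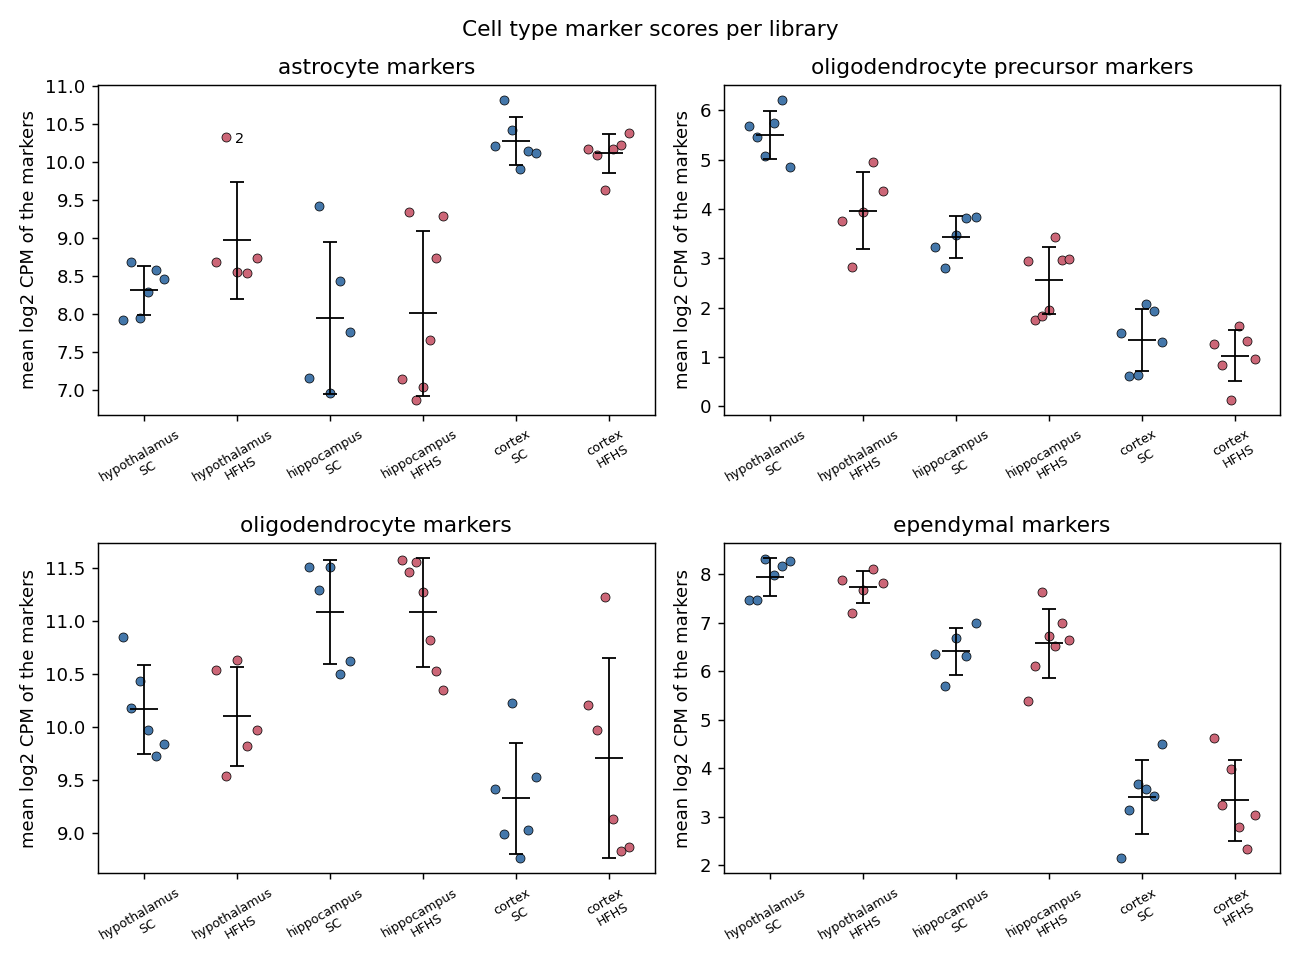
Cell type scores (mean log2 CPM of the marker genes, y axis) of each library by region and diet, with the mean and SD of each group. The astrocyte score on SC was highest in cortex (10.27) and the precursor score in hypothalamus was 5.50 on SC and 3.97 on HFHS.

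Markers of oligodendrocyte precursors, the dividing cells that give rise to myelinating oligodendrocytes, were lower in hypothalamus on HFHS than on SC. Gpr17, a receptor of committed precursors, had 27.0 ± 10.6 CPM (n = 5) on HFHS and 156 ± 85.2 CPM (n = 6) on SC, a log2 fold change of -2.53 ± 0.41 (SE). Pdgfra, the growth factor receptor that marks precursors, had 51.1 ± 28.4 CPM and 216 ± 111 CPM. Tnr, an extracellular matrix gene, had 11.9 ± 6.21 CPM and 37.0 ± 13.7 CPM, and Cspg4, which encodes the NG2 proteoglycan, had 24.8 ± 16.9 CPM and 76.7 ± 39.1 CPM. Of the 9 precursor markers, 8 were lower when adjusted over the list alone and 0 over all genes, with a median log2 fold change of -1.33. The list was lower by camera (adjusted p = 3.91e-11), but not when the correlation of its genes was estimated (adjusted p = 0.448 with an estimated correlation). Between 5 and 8 of the markers passed over the list alone when a replicate was left out, 5 without HFHS 1 and 5 without HFHS 3. The precursor score was 5.50 ± 0.49 on SC and 3.97 ± 0.79 on HFHS (exact permutation p = 0.00433, adjusted p = 0.182 over all lists and regions).

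Astrocyte and fat metabolism genes had higher means in hypothalamus on HFHS, in part through 1 library. Aldh1l1, a folate enzyme used as an astrocyte marker, had 196 ± 157 CPM on HFHS and 83.9 ± 22.0 CPM on SC, and Slc1a2, the main glutamate transporter, 542 ± 410 CPM and 238 ± 93.7 CPM. Of 18 astrocyte markers, 11 were higher when adjusted over the list alone and 0 over all genes (camera adjusted p = 1.51e-08, adjusted p = 0.466 with an estimated correlation). The 11 became 0 without SC 1, SC 3, SC 4, SC 5 or HFHS 2, 6 without SC 2 and 5 without SC 6, and the median of 0.84 became 0.29 without HFHS 2. That library had an astrocyte score of 10.33, and the others of its group lay between 8.54 and 8.74. Of 24 fatty acid oxidation genes, 7 were higher over the list alone and 0 over all genes (camera adjusted p = 4.02e-10, adjusted p = 0.466 with an estimated correlation), the 7 ranged from 2 to 11 as replicates were left out, and the median of 0.39 became 0.21 without HFHS 2. Acaa2, a thiolase of mitochondrial fat oxidation, had 140 ± 39.4 CPM on HFHS and 83.4 ± 13.3 CPM on SC, and Angptl4, a target of fatty acid receptors, 35.1 ± 27.1 CPM and 14.9 ± 3.44 CPM. Glycolysis genes had a median log2 fold change of 0.36 with 0 of 24 past the threshold over the list alone, 10 without SC 6 and 7 without HFHS 3, and the median was 0.19 without HFHS 2 (camera adjusted p = 3.09e-06, adjusted p = 0.466 with an estimated correlation). Gapdh, an enzyme of glycolysis, had 1650 ± 573 CPM on HFHS and 983 ± 159 CPM on SC. Antioxidant genes passed in 2 of 21 cases over the list alone (0 to 5 as replicates were left out), with Nqo1, a quinone reductase, at 27.4 ± 3.22 CPM on HFHS and 17.9 ± 2.24 CPM on SC (camera adjusted p = 1.84e-06, adjusted p = 0.466 with an estimated correlation).

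In the edgeR test of hypothalamus, 0 of 19272 genes passed the adjusted threshold and 1639 had an unadjusted p under 0.05, where chance alone gives 964. DESeq2 called 87 genes and voom 2. The 5 smallest p values belonged to Gpr17, Col11a2, Aldh1l2, Ptpro and Hap1, all lower on HFHS with an adjusted p of 0.333. Col11a2, a collagen gene, had 8.08 ± 3.72 CPM and 26.5 ± 8.30 CPM on SC, and Ptpro, a receptor phosphatase, 10.5 ± 3.05 CPM and 23.7 ± 4.65 CPM. Without SC 6, a library of short mean transcript length, 8 genes fell on HFHS and 0 rose, among them Gpr17, Col11a2, Aldh1l2 and Hap1 with an adjusted p of 0.0498 each. Gfap, the astrocyte filament gene, had 219 ± 103 CPM on HFHS and 124 ± 41.7 CPM on SC (adjusted p = 0.541), Aqp4, the endfoot water channel, 334 ± 224 CPM and 222 ± 46.8 CPM (adjusted p = 0.687), and Atp1b2 698 ± 669 CPM and 449 ± 110 CPM (adjusted p = 0.742).

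In hippocampus, precursor markers also had lower means on HFHS. Pdgfra had 13.8 ± 8.37 CPM (n = 7) on HFHS and 34.8 ± 17.9 CPM (n = 5) on SC, and Matn4, a matrix protein gene of precursors, 5.28 ± 2.51 CPM and 12.9 ± 4.87 CPM. Of the 9 markers, 2 were lower when adjusted over the list alone and 0 over all genes (camera adjusted p = 6.98e-05, adjusted p = 0.883 with an estimated correlation). The 2 became 0 without SC 4, SC 5 or HFHS 4, and 5 without HFHS 5. The precursor score differed by -0.88 (exact permutation p = 0.0379, adjusted p = 0.53), which was not told from the -1.53 of hypothalamus (difference -0.65, exact permutation p = 0.394, adjusted p = 0.928). Microglia markers had a median log2 fold change of 0.79 with 0 of 14 past the threshold over the list alone (camera adjusted p = 2.55e-07, adjusted p = 0.883 with an estimated correlation). The count was 8 without SC 5, 10 without HFHS 1 and 8 without HFHS 7, and the median was 0.44 without HFHS 4. C1qb, a complement gene of microglia, had 152 ± 95.6 CPM on HFHS and 74.2 ± 22.4 CPM on SC, and HFHS 4 reached 363 CPM. Of 10 mural cell markers, which label pericytes and vascular muscle, 4 were higher over the list alone (0 to 5 as replicates were left out), with Kcnj8, a potassium channel of pericytes, at 115 ± 37.4 CPM and 64.6 ± 23.1 CPM (camera adjusted p = 0.002, adjusted p = 0.883 with an estimated correlation). Fibroblast markers went both ways, 2 higher and 2 lower of 8 over the list alone (camera adjusted p = 0.866). Col3a1, a fibrillar collagen gene, had 1.82 ± 0.434 CPM on HFHS and 5.62 ± 2.29 CPM on SC (adjusted p = 0.497), and Slc6a13, a GABA and taurine transporter, 25.7 ± 10.8 CPM and 14.3 ± 3.54 CPM.

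The edgeR test of hippocampus called 0 of 19036 genes, with 984 at an unadjusted p under 0.05, where chance gives 952. DESeq2 called 15 genes and voom 0. Cdk17, a cyclin-dependent kinase gene, had the smallest adjusted p (0.497), with 54.7 ± 5.38 CPM on HFHS and 84.5 ± 4.23 CPM on SC. Acp2, a lysosomal phosphatase, had 31.6 ± 9.21 CPM and 64.0 ± 8.86 CPM, and Gfpt1, the first enzyme of hexosamine synthesis, 10.8 ± 3.43 CPM and 22.4 ± 3.21 CPM, with adjusted p values of 0.854 and 0.868. Gfap, Aqp4 and Atp1b2 had adjusted p values of 0.929, 0.98 and 0.918.

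In cortex, the smallest p values belonged to genes that were lower on HFHS, and the same genes varied between replicates of a single diet in hippocampus. Dapk3, a death-associated kinase, had 0.826 ± 0.540 CPM (n = 6) on HFHS and 21.2 ± 15.0 CPM (n = 6) on SC, a log2 fold change of -4.63 ± 0.71 (SE). Kctd2 had 7.44 ± 2.50 CPM and 48.1 ± 25.7 CPM, Rnf149, a ubiquitin ligase gene, 10.1 ± 4.58 CPM and 42.0 ± 13.2 CPM, Cdc34, a ubiquitin-conjugating enzyme, 9.70 ± 3.53 CPM and 36.6 ± 11 CPM, and Ssbp3, a cofactor of LIM domain transcription factors, 16.6 ± 5.52 CPM and 48.5 ± 8.52 CPM. All 5 had an adjusted p of 0.0576. Dapk3 ranged from 0.465 to 37.0 CPM within hippocampus on SC and from 0.417 to 38.1 CPM within hippocampus on HFHS, and the correlation with it among hippocampus libraries, with diet means subtracted, was 0.99 for Cdc34, 0.98 for Kctd2, 0.96 for Rnf149 and 0.96 for Ssbp3.

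The score of 219 genes that varied with Dapk3 in hippocampus was 4.71 ± 0.65 (n = 6) in cortex on SC and 3.13 ± 0.39 (n = 6) on HFHS. Dapk3 was taken up because of its diet difference in cortex, so that this difference of the score is no test of diet. In hypothalamus it was 4.63 ± 0.51 (n = 6) and 4.56 ± 0.48 (n = 5) (exact permutation p = 0.773), and in hippocampus 4.09 ± 1.25 (n = 5) and 3.77 ± 1.14 (n = 7) (exact permutation p = 0.683). The labels give no batch to set beside it. Both the score and its limits were chosen after the values were seen.

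**Figure D2:**
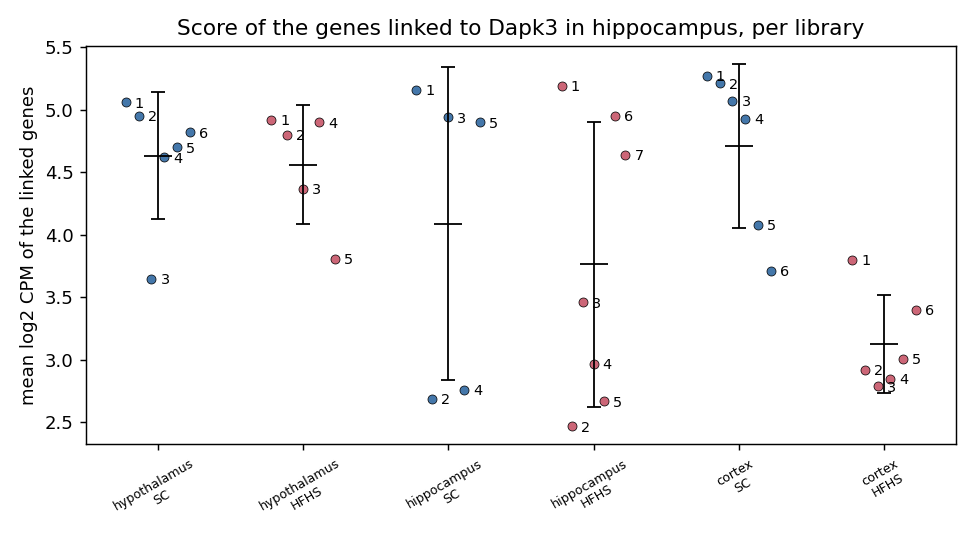
Score of the 219 genes that varied with Dapk3 in hippocampus (mean log2 CPM, y axis) in each library by region and diet, with the mean and SD of each group. Libraries of both diets spanned the range in hippocampus, and in cortex the SC mean was 4.71 and the HFHS mean 3.13.

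Genes of forebrain identity were among those lower in cortex on HFHS. Lhx2, a LIM homeobox transcription factor of the developing cortex, had 75.3 ± 43.4 CPM on HFHS and 203 ± 46.5 CPM on SC (adjusted p = 0.131), and Sox21 8.12 ± 8.4 CPM and 35.5 ± 28.9 CPM (adjusted p = 0.237). Of 11 telencephalon identity genes, 4 were lower when adjusted over the list alone (4 to 6 as replicates were left out) and 0 over all genes, with a median of -0.88 (camera adjusted p = 5.55e-05, adjusted p = 0.633 with an estimated correlation). Sox21 correlated with Dapk3 in hippocampus at 0.78 and Lhx2 at 0.44, and with the Dapk3-linked score as a covariate 0 of the 11 were lower over the list alone, where the median was -0.25. Diet accounts for a share of 0.722 of the variance of that score in cortex, so that this loss decides nothing about its source. All 76 ribosomal protein genes had lower fitted values on HFHS, with a median of -0.78 and 0 past the threshold (camera adjusted p = 1.14e-16, adjusted p = 0.919 with an estimated correlation). Rps2 had 84.3 ± 39.4 CPM on HFHS and 158 ± 43.4 CPM on SC. Over the list alone 60 of them fell without the cortex libraries numbered 6, and 72 without HFHS 6 alone, while the median was -1.2 without HFHS 6 and -0.24 without SC 6. With the Dapk3-linked score as a covariate 54 fell over the list alone, with a median of -1.64 (camera adjusted p = 5.81e-31, adjusted p = 0.83 with an estimated correlation). Antioxidant genes had a median of -0.53 with 0 of 21 past the threshold over the list alone, 11 without HFHS 6, 2 without SC 6 and 1 without HFHS 1, and the median was -0.21 without SC 6 (camera adjusted p = 7.67e-05, adjusted p = 0.919 with an estimated correlation). Gclc, the limiting enzyme of glutathione synthesis, had 30.9 ± 26.3 CPM on HFHS and 81.0 ± 27.5 CPM on SC. Respiratory chain genes had a median of -0.50 (camera adjusted p = 0.00189, adjusted p = 0.919 with an estimated correlation), which became 0.21 without SC 6 and -1.14 without HFHS 6.

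The edgeR test of cortex called 0 of 17844 genes, with 1652 at an unadjusted p under 0.05, where chance gives 892. The count depended on the libraries, on the tool and on the replicate block. With the replicate number as a block, whose meaning the labels do not give, edgeR called 412 genes. DESeq2 called 504 genes and voom 517. The edgeR count was 47 without SC 5, 141 without SC 6, 133 without HFHS 1 and 129 without HFHS 6, and 515 (207 higher, 308 lower on HFHS) without SC 6 and HFHS 6 together. The cortex libraries numbered 6 had mean transcript lengths of 1922 and 2179 bases, the shortest in the series. Without them, Dapk3 (adjusted p = 0.0125), Ssbp3 (0.0143) and Lhx2 (0.0271) fell on HFHS. With the Dapk3-linked score as a covariate the count was 0 with all libraries, with 884 at an unadjusted p under 0.05, and 0 without the 3 short libraries. Diet accounts for a share of 0.722 of the variance of the score in cortex, so that this covariate largely stands for diet there. Gfap, Aqp4 and Atp1b2 had adjusted p values of 0.858, 0.709 and 0.937.

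**Figure D3:**
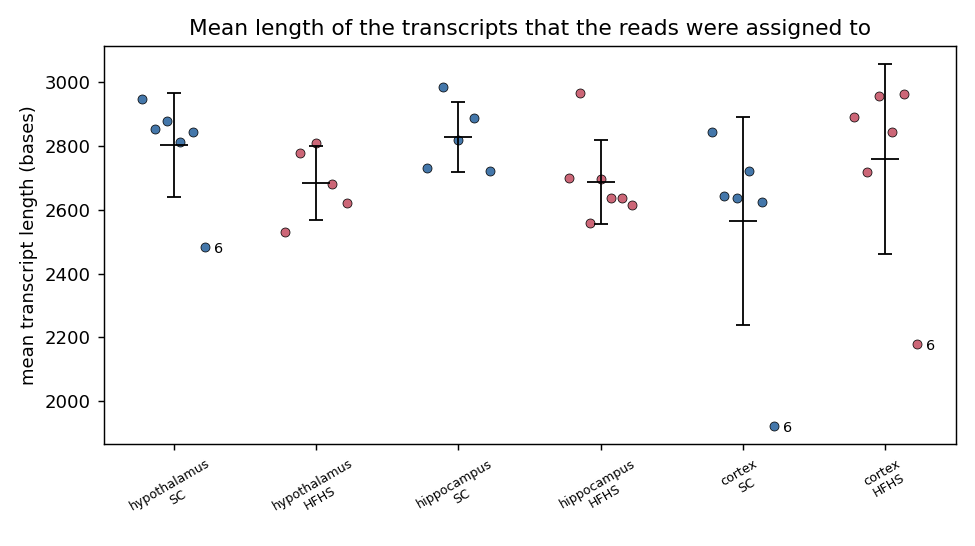
Mean length of the transcripts that reads were assigned to (bases, y axis) in each library by group, with the mean and SD. Cortex SC 6 (1922), cortex HFHS 6 (2179) and hypothalamus SC 6 (2483) lay below the other libraries, which ranged from 2530 to 2985.

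**Figure D4:**
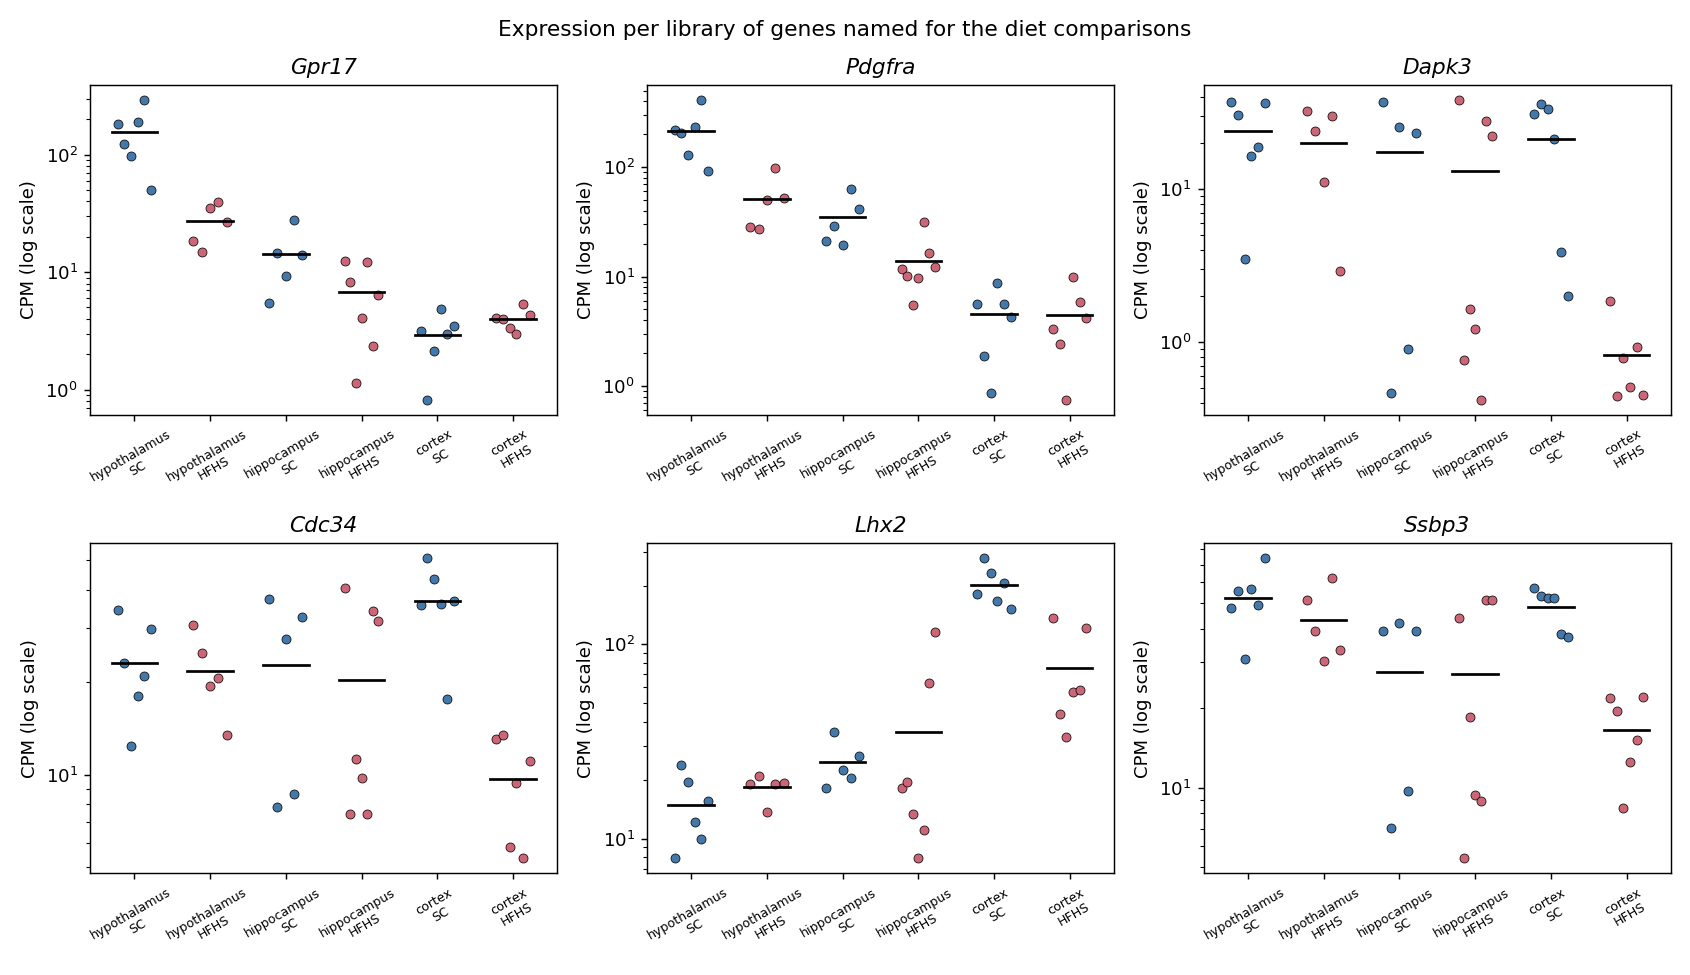
CPM of Gpr17, Pdgfra, Dapk3, Cdc34, Lhx2 and Ssbp3 (y axis, log scale) in each library by region and diet, with a line at the mean of each group. Gpr17 in hypothalamus averaged 156 CPM on SC and 27.0 CPM on HFHS, and Dapk3 in hippocampus spanned 0.465 to 37.0 CPM on SC.

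The interaction contrast asked whether the diet effect differed between regions. Between hypothalamus and cortex, the diet effect on Kdelr1, a receptor that returns proteins to the endoplasmic reticulum, differed by a log2 value of 1.5 ± 0.28 (SE), that on Rhoa, a small GTPase, by 1.16 ± 0.24, that on Wrn, a DNA helicase, by -1.67 ± 0.33, and that on Pcdh15, a protocadherin, by -2.73 ± 0.56. Their adjusted p was 0.105, and edgeR called 0 of 21574 genes, with 2496 at an unadjusted p under 0.05 (chance gives 1079). DESeq2 called 141 and voom 591. EdgeR also called genes with the replicate number within each diet as a block, as given further below. The count was 180 without cortex HFHS 6, 3 without cortex SC 6, 1 without cortex HFHS 1, 1 without hypothalamus HFHS 3, and 475 without the 3 short libraries. The interaction in these 475 genes correlated at 0.75 (Spearman, across genes, which are not independent replicates) with their slope on Dapk3 in hippocampus, and 432 of the 475 had the same direction (32 of 1000 permutations of Dapk3 within diet as high, permutation p = 0.033, permuted values from -0.84 to 0.81). With all libraries and the Dapk3-linked score as a covariate, edgeR called 0 genes, as without it, and 1576 had an unadjusted p under 0.05. This does not bear on the 475 genes, since the interaction was not fitted with the score and without the short libraries. Diet also accounts for a share of 0.722 of the variance of the score in cortex. Precursor markers had a more negative diet effect in hypothalamus than in cortex in 5 of 9 cases over the list alone, with a median of -1.76 (camera adjusted p = 0.000753, adjusted p = 0.784 with an estimated correlation), and in 2 of 9 with the Dapk3-linked score as a covariate. The diet differences of the precursor score, which was 1.34 on SC and 1.02 on HFHS in cortex, differed by -1.21 between these regions (exact permutation p = 0.0783, adjusted p = 0.928). Those of the astrocyte and tanycyte scores differed by 0.82 (exact permutation p = 0.022) and 0.69 (exact permutation p = 0.0218), with an adjusted p of 0.462 each.

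Between hippocampus and cortex, Hltf, a DNA translocase, had an interaction of -1.20 ± 0.25 (SE) and Gadd45b, a stress-induced gene, 1.76 ± 0.42, with an adjusted p of 0.44 each. EdgeR called 0 genes (2007 at an unadjusted p under 0.05), or 1 without hippocampus HFHS 2, DESeq2 23 and voom 2. Between hypothalamus and hippocampus, Acp2 had an interaction of 1.32 ± 0.35 (adjusted p = 1). EdgeR called 0 genes (433 at an unadjusted p under 0.05), DESeq2 4 and voom 0. Across 18341 genes, the diet fold changes of hypothalamus and hippocampus correlated at 0.26 (Spearman) and 0.25 (Pearson). As differences of mean log2 CPM they correlated at 0.28 and 0.27, and 7 and 1 of 100 splits with permuted diets were as far from 0. The Spearman correlation of the fold changes was -0.16 for hypothalamus and cortex and -0.07 for hippocampus and cortex. As differences of mean log2 CPM it was -0.16 and -0.04, and 44 and 84 of 100 splits were as far from 0. The diet fold changes also correlated with transcript length, at -0.19 in hypothalamus, -0.39 in hippocampus and 0.38 in cortex (Spearman). Whether length lies behind the correlations between regions was not tested.

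On SC, hypothalamus and cortex differed in genes of regional identity, of other cell types and of metabolism. Transcription factors of the hypothalamus were far higher than in cortex, with Nkx2-1 at 7.43 ± 2.15 CPM against 0.215 ± 0.0811 CPM in cortex, and Rax, which also marks tanycytes, at 17.9 ± 7.79 CPM against 0.866 ± 1.19 CPM (both n = 6). Of 9 such genes, 8 were higher over all genes (camera adjusted p = 2.94e-06, adjusted p = 0.00627 with an estimated correlation). Emx2 (0.821 ± 0.587 CPM against 33.7 ± 5.57 CPM) and Lhx2 (14.9 ± 6.01 CPM against 203 ± 46.5 CPM) were lower, as were 10 of 12 telencephalon genes (camera adjusted p = 2.61e-07, adjusted p = 0.0381 with an estimated correlation). Lower in hypothalamus were also Slc1a2 (238 ± 93.7 CPM against 4160 ± 1290 CPM) and Aldoc, the brain aldolase (1440 ± 574 CPM against 13000 ± 5410 CPM), with 15 of 18 astrocyte markers (camera adjusted p = 2.82e-08, adjusted p = 0.335 with an estimated correlation). Rpe65, the retinoid isomerase gene, fell by 7.63 on the log2 scale, and Chrdl1, a BMP antagonist of cortical astrocytes, by 6.34.

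Precursor and ependymal transcripts were higher in hypothalamus than in cortex. Gpr17 had 156 ± 85.2 CPM against 2.91 ± 1.36 CPM, and 8 of 9 precursor markers were higher (camera adjusted p = 1.02e-08, adjusted p = 0.0432 with an estimated correlation). The cilia genes Ccdc40 (148 ± 55.4 CPM against 1.94 ± 1.26 CPM) and Rsph1 (291 ± 79.6 CPM against 11.1 ± 5.88 CPM) were higher, with all 10 ependymal markers (camera adjusted p = 2.29e-12, adjusted p = 0.0432 with an estimated correlation). Immediate early genes, which respond within minutes to stimulation and to tissue dissociation, were higher in 17 of 22 cases, with Fos at 1320 ± 400 CPM against 104 ± 70.1 CPM (camera adjusted p = 7.9e-13, adjusted p = 0.143 with an estimated correlation). Cholesterol synthesis genes were lower in 21 of 24 cases, with Idi1 at 64.9 ± 10.4 CPM against 274 ± 49.6 CPM (camera adjusted p = 1.32e-14, adjusted p = 0.0432 with an estimated correlation). All 63 respiratory chain genes were lower, and 62 without the short libraries, with Atp5a1 at 465 ± 16.3 CPM against 888 ± 138 CPM (camera adjusted p = 8.67e-20, adjusted p = 0.335 with an estimated correlation). Mitochondrially encoded reads made up 3.14% (SD 1.42) of hypothalamus and 5.69% (SD 2.68) of cortex reads on SC. Cortex SC 6 had 10.95%, and the others of its group lay between 3.40% and 5.57%. Without the short libraries the estimated correlation left only the hypothalamus identity list past the threshold (adjusted p = 0.0259). EdgeR called 7782 of 21574 genes, 3827 higher and 3955 lower in hypothalamus, and 776 with the principal component of the cell type markers as a covariate, of which region accounted for a share of 0.917. Gfap (-1.95 ± 0.45, adjusted p = 0.00102), Aqp4 (-1.63 ± 0.41, 0.00234) and Atp1b2 (-1.25 ± 0.47, 0.0376) were lower, and Aqp4 and Atp1b2 turned positive with that covariate.

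Hippocampus on SC differed from cortex by more myelin and choroid plexus transcripts and fewer of astrocytes. Trf, the transferrin gene of oligodendrocytes, had 11800 ± 3500 CPM (n = 5) against 2500 ± 1050 CPM (n = 6), and 10 of 13 oligodendrocyte markers were higher (camera adjusted p = 2.56e-07, adjusted p = 0.209 with an estimated correlation). Otx2, a transcription factor of the choroid plexus, had 48.8 ± 42.4 CPM against 3.45 ± 4.09 CPM, with 6 of 8 choroid plexus markers higher (camera adjusted p = 0.00438, adjusted p = 0.413 with an estimated correlation). Ntsr2, a receptor of astrocytes, had 238 ± 218 CPM against 1860 ± 910 CPM, and 17 of 18 astrocyte markers were lower (camera adjusted p = 4.79e-13, adjusted p = 0.209 with an estimated correlation). Atp1b2 (270 ± 167 CPM against 1070 ± 368 CPM, adjusted p = 0.00405) and Aqp4 (adjusted p = 0.00124) were lower, while Gfap had 446 ± 263 CPM against 482 ± 274 CPM (adjusted p = 0.879).

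Telencephalon genes were lower in hippocampus in 7 of 12 cases and higher in 1, with Lhx2 at 24.7 ± 6.72 CPM against 203 ± 46.5 CPM (camera adjusted p = 0.000196, adjusted p = 0.201 with an estimated correlation). Crym, which binds thyroid hormone, had 4.17 ± 1.81 CPM against 126 ± 95.7 CPM. Fos had 1230 ± 156 CPM against 104 ± 70.1 CPM, among 16 of 22 immediate early genes that were higher (camera adjusted p = 4.79e-13, adjusted p = 0.201 with an estimated correlation). Genes of the unfolded protein response were higher in 9 of 20 cases, with the chaperone Hspa5 at 1480 ± 387 CPM against 765 ± 161 CPM (camera adjusted p = 0.014, adjusted p = 0.227 with an estimated correlation). Msmo1, of cholesterol synthesis, had 217 ± 73.1 CPM against 803 ± 322 CPM, with 19 of 24 genes of that pathway lower (camera adjusted p = 2.96e-11, adjusted p = 0.201 with an estimated correlation). EdgeR called 6636 genes, 3332 higher and 3304 lower in hippocampus, and 0 with the marker component as a covariate.

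Hypothalamus and hippocampus, processed on the same type of column, differed in regional, precursor, ependymal, tanycyte and choroid plexus genes. Gpr50, an orphan receptor of tanycytes, had 52.5 ± 24.5 CPM (n = 6) against 0.564 ± 0.5 CPM (n = 5), and Col25a1 25.5 ± 12.1 CPM against 0.608 ± 0.514 CPM. Of 11 markers of tanycytes, the glia that line the floor of the third ventricle, 7 were higher in hypothalamus (camera adjusted p = 3.52e-07, adjusted p = 0.0188 with an estimated correlation, or 0.0638 without the short libraries). Of 9 hypothalamus identity genes, 5 were higher (camera adjusted p = 2.07e-08, adjusted p = 0.000288 with an estimated correlation). Chga and Scg2, of secretory granules, had 84.6 ± 62.9 CPM against 3.81 ± 1.66 CPM and 108 ± 50 CPM against 7.77 ± 2.27 CPM. Precursor markers were higher in 8 of 9 cases and lower in 1, with Pdgfra at 216 ± 111 CPM against 34.8 ± 17.9 CPM (camera adjusted p = 3.2e-08, adjusted p = 0.064 with an estimated correlation). Ependymal markers were higher in 6 of 10 cases (camera adjusted p = 2.87e-07, adjusted p = 0.209 with an estimated correlation). Emx2 had 0.821 ± 0.587 CPM against 8.09 ± 4.31 CPM, among 5 of 12 telencephalon genes that were lower (camera adjusted p = 0.00128, adjusted p = 0.245 with an estimated correlation). Ttr, the transthyretin gene of the choroid plexus, had 96.5 ± 192 CPM against 9440 ± 8210 CPM, and 7 of 8 choroid plexus markers were lower (camera adjusted p = 1.17e-05, adjusted p = 0.459 with an estimated correlation). In hippocampus SC 3, Kl was at 1 CPM, where the other 4 libraries of its group had 137 to 715 CPM. EdgeR called 2157 genes, 1265 higher and 892 lower in hypothalamus, and 1298 without hippocampus SC 1. Gfap had a log2 difference of -1.84 ± 0.47 (adjusted p = 0.0101), Aqp4 0.33 ± 0.42 (adjusted p = 0.715) and Atp1b2 0.73 ± 0.5 (adjusted p = 0.405).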

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

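Of 498 groups of values tested (library measures, cell type scores and named genes), 59 held a library beyond Dixon's limit, and chance alone gives about 1 in 20 groups. The tests of transcript length, of depth and of co-variation with Dapk3 were chosen only after the result was seen. An earlier form of the last one, which divided the hippocampus libraries by their Dapk3 level, was dropped in favour of a slope over all of them.

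The cortex libraries numbered 6 stood apart in several measures. Cortex SC 6 had a mean transcript length of 1922 bases, against 2624 to 2843 in its group, and 10.95% mitochondrially encoded reads, against 3.40% to 5.57%. Cortex HFHS 6 had a mean length of 2179 bases, against 2719 to 2963. Among genes, cortex SC 6 was high in Cox8a (2600 CPM), Atp5d (906 CPM), Rps2 (245 CPM), Rpl32 (209 CPM), Rpl37a (206 CPM), Rps15a (76.3 CPM), Cldn10 (3130 CPM) and Rax (3.24 CPM), and low in Gclc (27.6 CPM), Gsr (27.6 CPM) and Pdia4 (94.9 CPM). Cortex HFHS 6 was high in Atp5d (507 CPM), Atp5e (176 CPM) and Sox21 (25 CPM).

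No gene was called by edgeR for diet in cortex with all libraries (1652 at an unadjusted p under 0.05, 504 called by DESeq2 and 517 by voom), and 515 without the libraries numbered 6, where the real split was 1 of 100 with as many and the highest other called 1, but that setting was chosen after the counts were seen and the splits do not exclude that diet and another structure of the libraries coincide by chance. Lower depth of the 2 libraries is argued against, since another cortex library had 47.58 M reads and the lower of the 2 had 54.61 M, and GC content is argued against as the whole cause, since 416 genes were called with an offset per GC bin, but it may have contributed, as the GC slopes of the 12 cortex libraries differed between the diets (-0.22, exact permutation p = 0.0433), the fold change without the libraries numbered 6 correlated with GC content at -0.27, and the median GC content was 55.8% for genes called lower and 47.5% for those called higher. Loss of long transcripts remains open, as the correlation of transcript length with the deviation from the other libraries was -0.40 or lower in both and at least 0.04 in each of the other cortex libraries. The cortex fold change itself correlated with transcript length at 0.38 with all libraries and still at 0.30 without those numbered 6. A dependence on length therefore remains in the 515 calls. Co-variation of the same genes for a reason other than diet remains open too, since over 514 of the called genes the cortex fold change correlated at 0.93 with the slope on Dapk3 in hippocampus (11 of 1000 permutations as high, permutation p = 0.012, permuted values from -0.95 to 0.95). The 514 genes were chosen by their cortex difference, and over all 17996 genes the correlation was 0.39. A response of cortical cells to the diet, which may have added to these differences, was not told from that co-variation, because diet accounts for a share of 0.722 of the variance of the Dapk3-linked score in cortex.

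Hypothalamus HFHS 2 had an astrocyte score of 10.33, against 8.54 to 8.74 in its group, and a mural cell score of 4.08, against 5.31 to 5.78. It was high in Aldoc (7430 CPM), Acsbg1 (1540 CPM), Pfkm (489 CPM), Aldh1l1 (477 CPM), Ldha (367 CPM) and Acaa2 (210 CPM). Hypothalamus SC 6 had a mean transcript length of 2483 bases, against 2813 to 2947, with Hap1 at 71.4 CPM and Cspg4 at 13.8 CPM below the others, and Gapdh at 1290 CPM and Uqcrfs1 at 116 CPM above them. Hypothalamus SC 1 was low in Gfap (50.6 CPM), Fosb (9.18 CPM), Egr1 (361 CPM) and Fos (534 CPM) and high in Glul (509 CPM). Hypothalamus SC 3 had a choroid plexus score of 4.65, against 0.67 to 2.10, with Sostdc1 at 13.9 CPM, Car12 at 10.3 CPM, Kcne2 at 6.79 CPM, Aqp1 at 3.10 CPM and Slc16a8 at 1.30 CPM above the others, and Idi1 at 44.6 CPM below them. Choroid plexus scores were also high in hypothalamus HFHS 3, HFHS 4 and HFHS 5 (6.03, 5.34 and 4.26), where HFHS 1 and HFHS 2 had 0.94 and 1.12. The GC slopes of the hypothalamus libraries differed between the diets as well (-0.1, exact permutation p = 0.0433). Hypothalamus SC 4 had a neuroblast score of 2.12, against 1.30 to 1.60. Hypothalamus SC 5 was low in Dlk1 (12.2 CPM) and Six6 (1.51 CPM).

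Hippocampus HFHS 2 had a mean transcript length of 2966 bases, against 2560 to 2700 in its group. Hippocampus HFHS 4 was high in the complement genes C1qb (363 CPM) and C1qc (315 CPM). Hippocampus SC 1 was low in Tnr (4.35 CPM), SC 3 in Kl (1 CPM) and Slc4a5 (0.328 CPM), and SC 5 in Jun (415 CPM), while SC 2 was high in Msmo1 (346 CPM). Cortex HFHS 3 had an astrocyte score of 9.63, against 10.10 to 10.38. Cortex SC 2 was high in Atp5b (2250 CPM), Atp5a1 (1160 CPM) and Idi1 (372 CPM), cortex SC 3 was high in Cfap221 (1.64 CPM), and cortex SC 5 was low in Cdc34 (17.6 CPM).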

How the results depend on the processing

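The settings chosen only after seeing the data were those without the 3 short libraries, with mean transcript length, with a GC offset and with the Dapk3-linked score. The cause of a change was not tested unless it is named. Of the settings tried on all libraries, only DESeq2 called diet genes in all 3 regions, and the cortex count moved most. In hypothalamus, DESeq2 called 87 genes for diet (23 higher, 64 lower), voom 2, the fit of all groups 1 and the fit without the short libraries 8. In hippocampus, DESeq2 called 15. In cortex, the count was 89 at an adjusted p of 0.10 (9 higher, 80 lower), 504 with DESeq2 (142 higher, 362 lower), 517 with voom (176 higher, 341 lower), 28 with DESeq2's size factors, 32 without the filter, 19 with length-scaled TPM, 310 with a surrogate variable, 461 with transcript length, 515 without the short libraries, and 416 with the GC offset as well. It stayed at 0 with the marker component, with all groups in the fit, with the GC offset alone and with the Dapk3-linked score. For the interaction of hypothalamus and cortex the count was 141 with DESeq2, 591 with voom, 475 without the short libraries and 1 with transcript length. For hippocampus and cortex it was 23 with DESeq2 and 2 with voom, and for hypothalamus and hippocampus 4 with DESeq2. With the marker component, the regions on SC gave 776 genes for hypothalamus against cortex and 0 for hippocampus against cortex, where the component itself follows region. Hypothalamus against hippocampus gave 5214 with voom, 3783 with the 2 SC groups alone and 3470 with transcript length.

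Leaving out each replicate gave 0 to 8 diet genes in hypothalamus, 0 to 0 in hippocampus and 0 to 141 in cortex, 0 to 180, 0 to 1 and 0 to 0 for the interactions (hypothalamus with cortex, hippocampus with cortex, hypothalamus with hippocampus), and 6872 to 7723, 5512 to 6776 and 1298 to 2184 for the regions in that order. Same-numbered replicates were checked for pairing. Their deviations correlated above 0.1 in 1 of 5 pairs in hypothalamus, 4 of 5 in hippocampus and 5 of 6 in cortex, and 3 of 10, 6 of 10 and 8 of 12 libraries correlated best with their own number. The labels do not say what the numbers mark, so that the main fits did not take them as pairs. Most pairs in hippocampus and cortex deviated together, although in no region did every pair pass 0.1. A shared source of same-numbered libraries is therefore not excluded, and the main counts treat them as independent. Libraries of different regions may also come from the same mice. With the replicate number as a block, 412 genes were called for diet in cortex. For the interaction of hypothalamus and cortex the block was the number within each diet, which ties same-numbered libraries of different regions, and 299 genes were called. The check of pairs within a region does not bear on that block.

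Of the 41 lists, camera passed 20, 7 and 6 for diet in hypothalamus, hippocampus and cortex, and 0 in each with an estimated correlation or fry. For the interactions 12, 5 and 12 became 0 under both. For the regions, 22, 25 and 14 became 5, 0 and 2 with an estimated correlation, and 29, 25 and 7 with fry. No cell type score passed as log2 CPM, as TPM or without the short libraries. The correlation of the diet effects of hippocampus and cortex was 0.02 as Pearson's r, of opposite sign to Spearman's. Among genes named for diet, 1657 of 1818 values kept side and direction, 138 newly passed the threshold and 23 changed sign. Of 848 for the interactions, 801 stayed, 34 newly passed and 13 changed sign, and of 3219 for the regions, 3118 stayed, 90 no longer passed and 11 changed sign.

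Signs changed for these genes. For diet in hypothalamus, Atp1b2 was -0.04 with voom and -0.16 to 0.84 with replicates left out. For diet in hippocampus, transcript length gave 0.32 for Gfap and 0.28 for Atp1b2, the block -0.38 for Aqp4, and replicates left out gave -0.52 to 0.07 for Gfap, -0.13 to 0.58 for Aqp4 and -0.76 to 0.04 for Atp1b2. For diet in cortex, the Dapk3-linked score, which largely stands for diet there, gave Gclc 0.37, Gsr 0.23, Gclm 0.30, Gfap 1.18 and Atp1b2 0.95, and, without the short libraries, Sox21 0.60, Gclc 0.11, Gclm 0.46, Gfap 0.67, Aqp4 0.14 and Atp1b2 1.07. For the interaction of hippocampus and cortex, Gfap was -0.24 with voom, -0.27 with the block, -0.03 with the GC offset and -0.13 to 0.50 with replicates left out, and Atp1b2 was 0.38 with transcript length and -0.55 to 0.24 with replicates left out. For hypothalamus and hippocampus, Aqp4 was -0.02 to 0.68. With the marker component, Aldoc was 0.05, Aqp4 0.19 and Atp1b2 0.34 between hypothalamus and cortex, and Trf -0.81, Mag -1.17, Mal -1.27 and Gfap 1.20 between hippocampus and cortex, where Gfap was also -0.48 to 0.14 with replicates left out. The hippocampus astrocyte score was -0.06 with TPM and -0.19 to 0.43 with replicates left out. Depth limits genes with few reads, and in the simulation on cortex most changes of 2-fold were missed.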

Other observations

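The test of cell shares between regions was chosen only after the result was seen, as were the library structure described last and the comparison without the choroid plexus score.

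Several other gene groups differed between the regions on SC. Mitochondrially encoded genes were lower than in cortex in 13 of 13 cases in hypothalamus (median log2 difference -1.33, camera adjusted p = 4.43e-06, adjusted p = 0.36 with an estimated correlation) and in 13 of 13 in hippocampus (-1.53, camera adjusted p = 7.85e-08, adjusted p = 0.227 with an estimated correlation). Genes of glutamate, GABA and potassium handling were lower in 14 of 19 cases in hypothalamus (camera adjusted p = 2.26e-06, adjusted p = 0.335 with an estimated correlation) and in 14 of 19 in hippocampus, where 1 was higher (camera adjusted p = 5.51e-10, adjusted p = 0.209 with an estimated correlation). Fatty acid oxidation genes were lower than in cortex in 20 of 24 cases in hypothalamus, where 1 was higher, and in 13 of 24 in hippocampus (camera adjusted p = 9.3e-09 and 4.44e-06, adjusted p = 0.153 and 0.209 with an estimated correlation). Synaptogenic and matrix genes were lower in 11 of 21 cases and higher in 2 in hypothalamus, and lower in 13 and higher in 2 in hippocampus (camera adjusted p = 0.000204 and 2.1e-06, adjusted p = 0.345 and 0.209 with an estimated correlation).

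The lower precursor markers in hypothalamus on HFHS were weighed against a lower share of all other cells. Such a shift would lower every other marker list alike. The precursor score minus the mean of the 12 other scores was 0.61 ± 0.54 (n = 6) on SC and -1.01 ± 0.37 (n = 5) on HFHS, a difference of -1.62 (exact permutation p = 0.00433). It was -1.47 (exact permutation p = 0.00649) without the choroid plexus score, which was itself 1.69 higher on HFHS (exact permutation p = 0.169). The precursor markers thus fell further than the mean of the other lists in these libraries. However, the precursor list had the smallest exact permutation p of all lists and regions. The p values of this difference are not adjusted for that choice, so that they do not exclude such a shift. The short library SC 6 is argued against as the cause, since the difference of the precursor score was -1.66 without it and -1.53 with it. Fewer precursors in the sorted fraction, or fewer of their transcripts per cell, may account for the difference, and these data do not separate them. The score missed the threshold over all lists and regions (adjusted p = 0.182), so that this is a hypothesis.

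The lower respiratory chain and mitochondrially encoded genes in hypothalamus and hippocampus were weighed next. The short libraries are argued against as the cause, since 53 of the respiratory chain genes were lower in hippocampus without them and 59 with them. A different share of other cells could be a source of the difference, and it cannot be told apart from region, because region accounts for a share of 0.917 of the variance of the marker component. The column type and reagent volumes, which also follow region in the comparisons with cortex, cannot be told apart from it either. A difference of the astrocytes themselves between regions remains open and untested.

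Splits of the same libraries set the diet and region counts against chance. With 0 genes called for diet by edgeR in each region, every split gives as many by construction (100 of 100 in hypothalamus, 100 of 100 in hippocampus and 100 of 100 in cortex), so that the splits decide nothing about these counts and chance is not excluded (1639, 984 and 1652 genes at an unadjusted p under 0.05, and 87, 15 and 504 called by DESeq2, 2, 0 and 517 by voom). The highest other splits called 52, 1008 and 1 genes. The split with 1008 set the 7 hippocampus libraries with the highest astrocyte scores (7.66 to 9.42) against the other 5 (6.87 to 7.16). It also kept the libraries numbered 2 and 5 of both diets on the same side, and those numbered 1 and 3 of both diets together on the other. Those numbered 4 were divided. It was looked at because its count was the highest, and its source was not tested. The one with 52 in hypothalamus set SC 1, SC 2, SC 6, HFHS 1 and HFHS 4, which had the 5 highest Dapk3-linked scores of hypothalamus, against the rest. Its source was not tested either. For the interactions, 60 of 60 splits likewise gave as many as the 0 called by edgeR by construction, which decides nothing either (2496, 2007 and 433 at an unadjusted p under 0.05, 141, 23 and 4 by DESeq2, 591, 2 and 0 by voom). Of the other splits, 2, 8 and 7 called any gene. The highest called 188, 1301 and 340, and which libraries they grouped was not examined. For the regions on SC, the real split alone reached its count (1 of 25 each) at 7782, 6636 and 2157 genes, with the highest others at 1445, 1653 and 58. This argues against chance, but 1 of 25 is the smallest share that so few splits can give, so that chance is not excluded.

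The co-variation with Dapk3 was also seen in hypothalamus. There, the slope on Dapk3 of the same 514 genes correlated with the cortex fold change at 0.85, and 452 had the same direction (13 of 1000 permutations of Dapk3 within diet as high, permutation p = 0.014, permuted values from -0.85 to 0.88). In hippocampus 503 of the 514 had it. Of the 219 genes in the score, 132 were called lower on HFHS in cortex without the short libraries and 0 higher, and their median GC content was 54.8%, against 49.3% for all genes. The correlation with Dapk3 in hippocampus was -0.25 for Gpr17 and -0.24 for Pdgfra, the precursor genes lower in hypothalamus. Together with the correlation of 0.93 in hippocampus, this suggests that the genes that differed in cortex also vary together between libraries of a single diet in hypothalamus and hippocampus. A handling or sequencing batch that the labels do not give, a shared state of the cells or a response to diet could each be the source of the cortex differences, as diet accounts for a share of 0.722 of the variance of the score. No test in these data separates them.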
